A study of Mus musculus with 2 samples.

How the data were processed

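Binding of p300 was measured by chromatin immunoprecipitation and sequencing in heart and in midbrain of CD-1 mouse embryos at embryonic day 11.5. p300 is a histone acetyltransferase and transcriptional coactivator that is found at many active enhancers. Per the labels, each tissue is represented by 1 library made from material of about 150 embryos of both sexes. The immunoprecipitated DNA was amplified, selected on a gel at 300 to 500 bp and read on an Illumina Genome Analyzer as 36 bp reads, per the labels' protocols. The shared protocol text names forebrain, midbrain and limb and does not name heart, so the dissection of the heart is not described in the sources used here.

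For each tissue the authors deposited aligned reads, a coverage track and a peak list, all on the mouse build mm9 per the file headers and the submitters' processing notes. The aligned reads are positions with 1 read per line, and the authors lengthened nearly every read to 300 bp, as checked on the positions themselves (all but 24 heart and 48 midbrain lines). No position and strand occurred more than once in either library, so repeated reads had been collapsed before deposit. The coverage track that the authors deposited holds signal (coverage) as whole numbers at 25 bp steps, made from unique reads lengthened to 300 bp per the file headers, and it is not scaled to library size. Its sum was 100.335% of the value expected from the aligned reads in the heart and 100.336% in the midbrain. The word blat stands in the track names of the heart library, per the file headers. The aligner of the midbrain library, the peak caller, its thresholds and any control were not given in the sources used here. Each deposited peak list gives start, end and a rank, with no height, fold or score, so the description by the authors' score that had been planned was replaced by one by rank. Peaks were listed separately for each tissue.

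The following was computed from these files with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1. A read was placed by moving its 5 prime end by 23 bp in the heart and 34 bp in the midbrain. These shifts came from offsets between the strands of 47 and 69 bp, estimated within peaks and searched from 46 to 500 bp. The lower limit of that search was set after the strand profiles had been seen, and the heart estimate lies next to it. Both estimates lie far below the size range selected on the gel. They serve as shifts and not as measured fragment lengths, and a shifted read need not lie at the middle of its fragment. Reads were scaled to all aligned reads of a library and are given as rpm, the usual library-scaled unit. Ratios of reads carry exact conditional binomial 95% intervals and shares carry exact Clopper-Pearson 95% intervals. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. A ratio against a count of 0 is given by the bound of its interval alone. The limit that a count of 0 allows was taken as 3 reads, equal to 2.30 rpm in the heart and 0.511 rpm in the midbrain. With 1 library per tissue no test between tissues was possible and no p-value is given. Every statement about a tissue is a statement about its library.

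Peaks were called shared when they overlapped by at least 1 bp. Random expectations came from 1000 placements of the peaks within their own chromosomes in 10 kb bins that hold reads. Such placements treat peaks as independent of one another. Enrichment was the read density in peaks divided by the density in flanks 5 to 10 kb away on each side, with 100 random placements for comparison. Clustering was the share of peaks with another peak of the same list within 50 kb, centre to centre. Peaks per chromosome were compared with the share of reads on chromosomes 1 to 19 and X. The interval method was run on simulated data with known folds of 1, 2 and 8 at the read depths of the real peaks, and its intervals held the simulated fold in 97.4% to 98.9% of peaks. The simulated counts followed the counting model that the intervals assume. This therefore checks the computation and does not show how often the intervals hold for real reads.

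Peaks named by position followed a rule fixed before the data were examined. It took, per tissue, the 10 peaks outside the other list with the highest lower bound of the read ratio among peaks with at least 20 reads, and the 3 shared peaks with the highest rpm summed over both libraries. The rule did not say which reads the minimum of 20 counts. It was applied to the sum over both libraries after the low counts of the heart library had been seen, which favours heart peaks that also hold midbrain reads and left 77 heart and 1043 midbrain peaks to choose from. The minimum of 5 peaks that defines a run was set after the data had been seen, and runs and dense windows named by position were chosen after their values had been seen. The rule names no peak on chromosome 18, where some peaks have lower bounds above those of named peaks, so the named peaks are not the highest of all chromosomes.

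Alternatives fixed beforehand were other overlap criteria, the better-ranked part of each list, equal list lengths, another scale, no shift, thinning of the midbrain reads to the heart total, the coverage track in place of the reads, other flanks and another clustering distance. A shift of 150 bp and the joining of peaks less than 1 kb apart were added after the data had been seen. Planned comparisons with gene lists, distances to transcription start sites and sequence motifs were not run. The gene table at hand names the assembly GRCm38.p6 and the peaks are on mm9, coordinates were not converted, and no genome sequence was used here. Peaks are therefore given by mm9 position without genes. Sequence conservation, which the title of the series refers to, was not analysed here.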

Results

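p300 binding was mapped in mouse heart and midbrain at embryonic day 11.5, with 1 library per tissue and therefore no replicate check on any difference. The heart library held 1303861 aligned reads and the midbrain library 5869671, which is 4.50 times as many. A single read was thus worth 0.767 rpm in the heart and 0.170 rpm in the midbrain. Chromosomes 1 to 19 and X took 99.6% of the reads of each library. All 36 bases were aligned for 93.1% of the heart reads and 86.0% of the midbrain reads.

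The first question was how many regions each tissue's list holds and how strongly they are covered. The heart list held 3597 p300 peaks and the midbrain list 2786. Heart peaks had a median width of 662 bp (quartiles 540 and 790 bp) and covered 2.47 Mb in all, and midbrain peaks had a median width of 743 bp (quartiles 575 and 999 bp) and covered 2.36 Mb. The heart peaks rested on fewer reads, with a median of 6 heart reads per peak (quartiles 5 and 7, range 1 to 33) against 17 midbrain reads per midbrain peak (quartiles 13 and 24, range 5 to 153). Only 10 heart peaks held 20 or more heart reads, while 1044 midbrain peaks held 20 or more midbrain reads. The deposited rank followed the read number. Across peaks, the Spearman correlation of rank with reads was -0.80 in the heart and -0.94 in the midbrain, where rank 1 is the best, and that of rank with width was -0.18 and -0.73. Peaks within a library are not independent replicates, and the lists were made at different depths.

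The lists were then compared by position. Few p300 peaks were common to the heart and midbrain lists: 154 heart peaks (4.28%, interval 3.64 to 4.99) overlapped a midbrain peak, and 155 midbrain peaks (5.56%, interval 4.74 to 6.48) overlapped a heart peak. This was 23.7 times the mean of 6.49 heart peaks in random placements, which ranged from 0 to 16. Better-ranked peaks were shared more often, and they were also wider, which by itself raises the chance of an overlap of 1 bp. Among heart peaks of rank 1 to 500, 9.6% were shared (interval 7.16 to 12.5), and among those beyond rank 2000, 2.82% (interval 2.06 to 3.75), with median widths of 851 and 621 bp. In the midbrain list the share was 8.6% for rank 1 to 500 (interval 6.29 to 11.4) and 4.33% beyond rank 2000 (interval 3.01 to 5.99), with median widths of 1258.5 and 547 bp. The effect of rank apart from width was not tested. The share depends on what counts as overlap, and with a reciprocal overlap of 50% it was 2.06% of the heart peaks. Sites missed by the calling in either library also lower it, so a peak in only 1 list need not be absent from the other tissue. The interval of the read ratio between the libraries included 1 at 2034 of the 2631 midbrain-only peaks and at 261 of the 3443 heart-only peaks.

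The reads at the peaks were compared next, to see how far each tissue's regions differ in the other tissue. At the 3443 peaks found only in the heart list, the heart library had 9.34 times the library-scaled reads of the midbrain library (interval 9.12 to 9.56), with a mean of 4.81 rpm per peak against 0.515 rpm. At the 2631 peaks found only in the midbrain list, the midbrain library had 4.29 times the library-scaled reads of the heart library (interval 4.13 to 4.46), with 3.49 rpm against 0.813 rpm. Peak by peak, the interval lay on the heart side for 3182 heart-only peaks (92.4%) and on the midbrain side for 597 midbrain-only peaks (22.7%). No heart-only peak had an interval on the midbrain side, and no midbrain-only peak had one on the heart side. The peaks were picked from these same reads, so the ratios are not independent evidence of a difference. Depth limits the count on the midbrain side: 1130 midbrain-only peaks (42.9%) held 0 heart reads, and in simulated data an 8-fold difference was called for 30.5% of midbrain peaks and 76.4% of heart peaks. The simulation redrew the own-tissue counts without the selection that real listed peaks passed, so its rates are only a rough guide. Over all 3597 heart peaks, with a pooled ratio of 7.95, the interval lay on the heart side for 89.9%. With midbrain reads thinned to the heart total, 1148 of the 3443 heart-only peaks had an interval on the heart side and 399 of the 2631 midbrain-only peaks one on the midbrain side. The lists were not made anew from the thinned reads. Midbrain peaks were picked at full depth and heart peaks from the very reads counted here, so these counts are not an equal comparison.

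Of the 10 heart-only peaks that the naming rule picked, all with at least 20 reads over both libraries, the one with the highest lower bound lay on chromosome 5 at 122542479 to 122544058 (mm9), with 23 heart reads and 2 midbrain reads and a heart over midbrain ratio of 51.8 (interval 12.8 to 453). Another lay on chromosome 8 at 35015847 to 35017071, with 19 and 4 reads and a ratio of 21.4 (interval 7.11 to 86.4), and another on chromosome 12 at 70858270 to 70860054, with 21 and 5 reads and a ratio of 18.9 (interval 6.94 to 64.2). The other 7 named heart peaks had lower bounds of the ratio from 5.04 to 6.56. They lay on chromosome 17 at 12397126 to 12398601, chromosome 2 at 172860367 to 172861657, chromosome 9 at 63892737 to 63893592, chromosome 6 at 122343654 to 122344671, chromosome 14 at 63865095 to 63866896, chromosome 11 at 102236217 to 102237632, and chromosome 8 at 59801392 to 59802698. Their ranks in the heart list ran from 11 to 114. Heart counts at these 10 peaks were between 16 and 23 reads, so the size of each ratio is known only within wide bounds. The minimum of 20 reads left out heart peaks with few midbrain reads: on the chromosomes the rule covers, 217 heart-only peaks below it had a lower bound above 5.04, the lowest among those named, and 143 of these held no midbrain read. The highest lower bounds among them, picked out after their values had been seen, were 17.4 on chromosome 3 at 104403070 to 104403959 (16 heart reads) and 14.9 on chromosome 19 at 36203893 to 36204947 (14 heart reads), each with 0 midbrain reads.

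Of the 10 named midbrain-only peaks the highest lower bound was at chromosome 9, 51953261 to 51958067 (mm9). This peak is also the widest of the midbrain list (4807 bp) and held 153 midbrain reads against 1 heart read, a midbrain over heart ratio of 34.0 (interval 6.01 to 1351). Chromosome 1 at 179080039 to 179081973 held 104 midbrain reads and 1 heart read (ratio 23.1, interval 4.06 to 921). Chromosome 13 at 36373670 to 36376381 held 121 and 2 reads (ratio 13.4, interval 3.64 to 112), and chromosome 10 at 38272411 to 38274729 held 109 and 2 reads (ratio 12.1, interval 3.27 to 101.2). The other 6 named midbrain peaks held no heart read. Chromosome 4 at 22761717 to 22764161 had 78 midbrain reads, and the lower bound of its midbrain over heart ratio was 4.59. The remaining 5 had 56 to 58 midbrain reads and lower bounds from 3.26 to 3.38. They lay on chromosome 12 at 71523162 to 71524385 and 55016249 to 55018702, and on chromosome 3 at 5236357 to 5238181, 49690044 to 49691179 and 137345989 to 137347316.

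Shared peaks were listed from the reads of both libraries, so a ratio nearer to 1 there follows in part from how they were selected. At the 154 heart peaks that overlap a midbrain peak the heart library had 2.25 times the library-scaled reads of the midbrain library (interval 2.10 to 2.41). Measured over the 155 overlapping midbrain peaks, whose boundaries differ, the ratio was 1.19 (interval 1.11 to 1.28). The interval lay on the heart side at 53 of the shared heart peaks and included 1 at the others, and at the shared midbrain peaks it lay on the heart side at 13 and on the midbrain side at 4. The named shared peaks had the highest rpm summed over both libraries and are given within heart-list boundaries. A heart read counts for more in that sum (0.767 rpm against 0.170 rpm), so the choice leans towards sites with many heart reads. The highest sum was at the top-ranked heart peak, on chromosome 13 at 81023719 to 81025344 (mm9). It held 33 heart and 55 midbrain reads (25.3 and 9.37 rpm, ratio 2.70, interval 1.70 to 4.23). Its midbrain partner has rank 9. The next were on chromosome 5 at 143579139 to 143581745, with 29 heart and 48 midbrain reads (ratio 2.72, interval 1.65 to 4.40), and on chromosome 6 at 136416804 to 136417837, with 23 and 25 reads (ratio 4.14, interval 2.25 to 7.60). Their midbrain partners have ranks 463 and 308.

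Read density in peaks was also set against the density 5 to 10 kb away, which serves as the background within each library. Heart reads were 9.57 times as dense at heart-only peaks as in the flanks (interval 9.41 to 9.74), and midbrain reads were 6.82 times as dense at midbrain-only peaks (interval 6.75 to 6.89). The peaks were picked from these same reads, so an excess of a library at its own peaks follows from selection. Heart peaks were also picked at lower read numbers, so the values of the libraries are not on equal terms. Reads of the other tissue also lay above their flanks. Midbrain reads were 1.62 times as dense at heart-only peaks (interval 1.58 to 1.65), and heart reads 1.85 times as dense at midbrain-only peaks (interval 1.78 to 1.92). Random placements gave means of 1.0045 for heart reads and 1.0014 for midbrain reads at positions drawn for heart-only peaks, with highest values of 1.37 for heart reads and 1.13 for midbrain reads. Positions drawn for midbrain-only peaks gave means of 0.996 for heart reads and 1.0004 for midbrain reads, with highest values of 1.27 and 1.14. At shared heart peaks the enrichment was 10.4 for heart reads (interval 9.65 to 11.2) and 5.76 for midbrain reads (interval 5.49 to 6.04). Within the boundaries of the shared midbrain peaks it was 7.01 for heart reads (interval 6.46 to 7.60) and 7.33 for midbrain reads (interval 7.03 to 7.64), so the gap between the libraries at shared sites depends on the list that sets the boundaries. Peaks took 1.75% of the heart reads (heart list, interval 1.73 to 1.78) and 0.981% of the midbrain reads (midbrain list, interval 0.973 to 0.989).

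**Figure D1:**
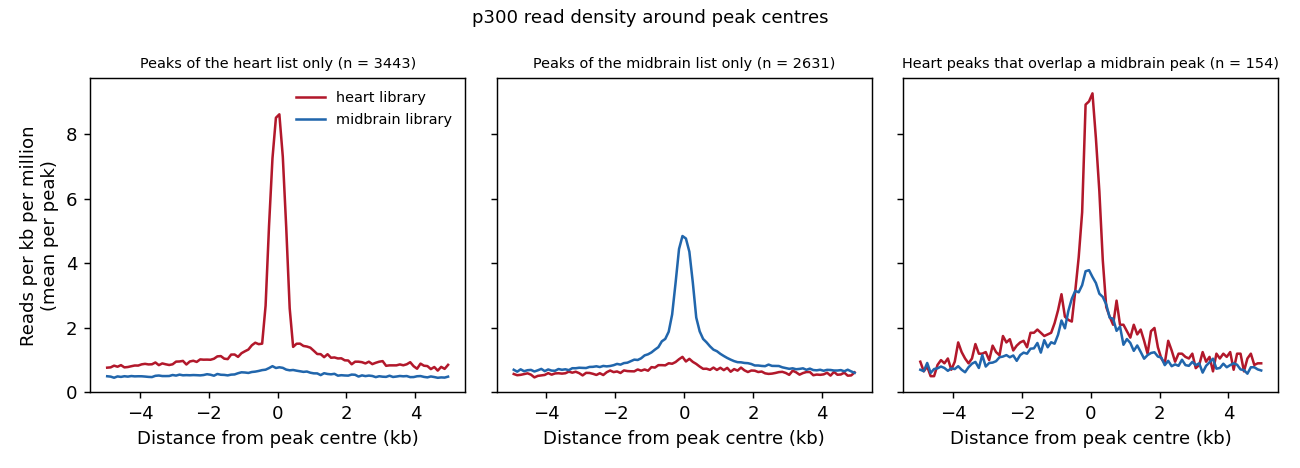
Mean read density (rpm per kb for each library, vertical axis) against distance from the peak centre in kb (horizontal axis) for 3443 heart-only peaks, 2631 midbrain-only peaks and 154 heart peaks that overlap a midbrain peak; red lines are the heart library and blue lines the midbrain library. The highest mean is 8.61 for heart reads at heart-only peaks and 4.84 for midbrain reads at midbrain-only peaks, and at shared peaks the heart line reaches 9.26 and the midbrain line 3.78.

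The p300 peaks of each tissue lay close to one another along the chromosomes. In the heart, 1608 peaks (44.7%, interval 43.1 to 46.3) had another heart peak within 50 kb, against a mean of 14.1% in random placements (range 11.7 to 16.9). In the midbrain, 1197 peaks did so (43.0%, interval 41.1 to 44.8), against 11.2% (range 8.47 to 13.9). Runs of at least 5 peaks, each within 50 kb of the next, numbered 46 in the heart and held 285 peaks, and 34 in the midbrain with 223 peaks. No random placement gave more than 2 such runs for the heart list or more than 1 for the midbrain list. Part of the clustering came from peaks less than 1 kb apart: with these joined, 40.0% of heart and 33.9% of midbrain regions had a neighbour, against random maxima of 15.9% and 13.0%. Runs were counted on the peaks as listed, in the data and in the placements, and were not counted again after this joining.

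The longest heart run by number of peaks, on chromosome 8 at 59792692 to 59880323 (mm9), held 14 heart peaks over 87.6 kb and no midbrain peak. It was followed by runs of 10 heart peaks on chromosome 17 at 12917533 to 12987506 and on chromosome 1 at 73952260 to 74115687, each without a midbrain peak. The longest midbrain run by number of peaks, on chromosome 4 at 22404154 to 22426142, held 13 midbrain peaks over 22.0 kb and no heart peak. In the longest heart run and the longest midbrain run, several neighbouring peaks lie less than 1 kb apart. Joining such peaks would lower the peak numbers of these runs. Other runs held peaks of both lists. The region on chromosome 2 at 17947588 to 17985722 held 11 midbrain and 5 heart peaks, and the one on chromosome 7 at 80684893 to 80764251 held 8 heart and 4 midbrain peaks. These runs were picked out after their values had been seen, by the number of peaks and by the presence of the other list.

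**Figure D2:**
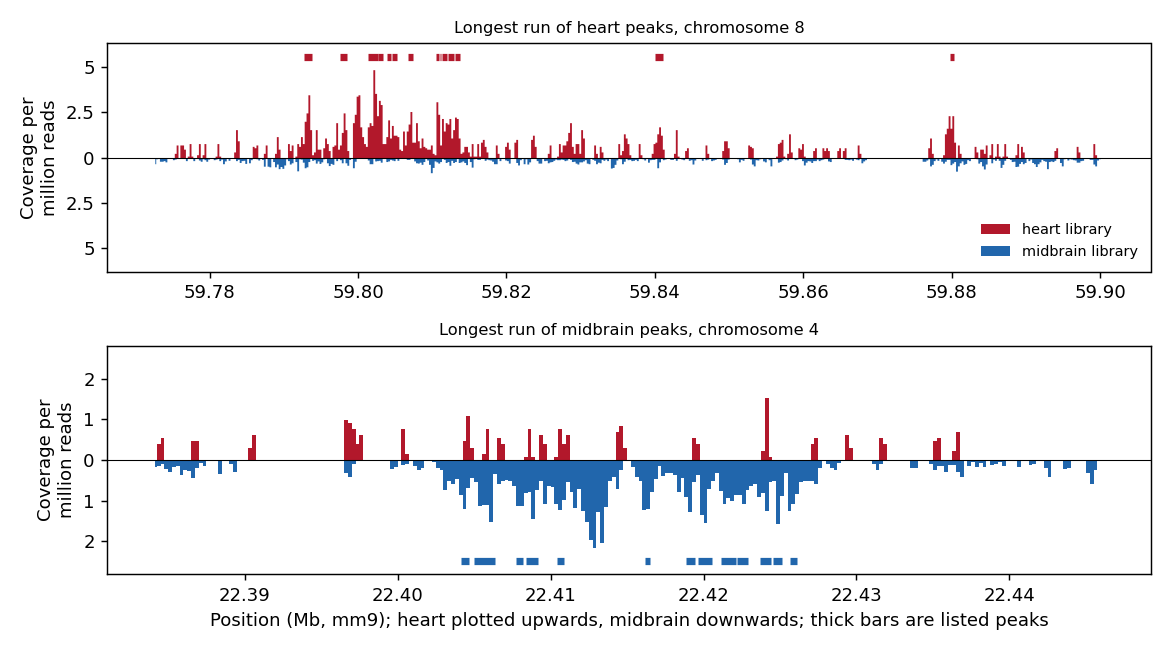
Coverage scaled to the total reads of each library as in rpm (vertical axis, heart drawn upwards in red and midbrain downwards in blue, each panel with its own scale). The panels show the longest runs by number of peaks, of heart peaks on chromosome 8 and of midbrain peaks on chromosome 4. The horizontal axis is the mm9 position in Mb, and thick bars are the listed peaks. The heart run holds 14 heart peaks and 0 midbrain peaks, and the midbrain run holds 13 midbrain peaks and 0 heart peaks.

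Peaks were last compared with the reads of each chromosome. Chromosome X held few p300 peaks in either tissue: 21 heart peaks where its share of reads predicts 108 (ratio 0.194, interval 0.120 to 0.297), and 27 midbrain peaks where 104 are predicted (ratio 0.260, interval 0.172 to 0.378). Chromosome 13 held 221 midbrain peaks against 133 predicted (ratio 1.66, interval 1.45 to 1.88), and its ratio for heart peaks was 1.13 (interval 0.984 to 1.301). Chromosome 11 held 264 heart peaks against 205 predicted (ratio 1.29, interval 1.14 to 1.45), and its ratio for midbrain peaks was 1.103 (interval 0.939 to 1.29). Whether a chromosome differs between the lists was not tested. Because peaks cluster, the binomial intervals are too narrow.

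**Figure D3:**
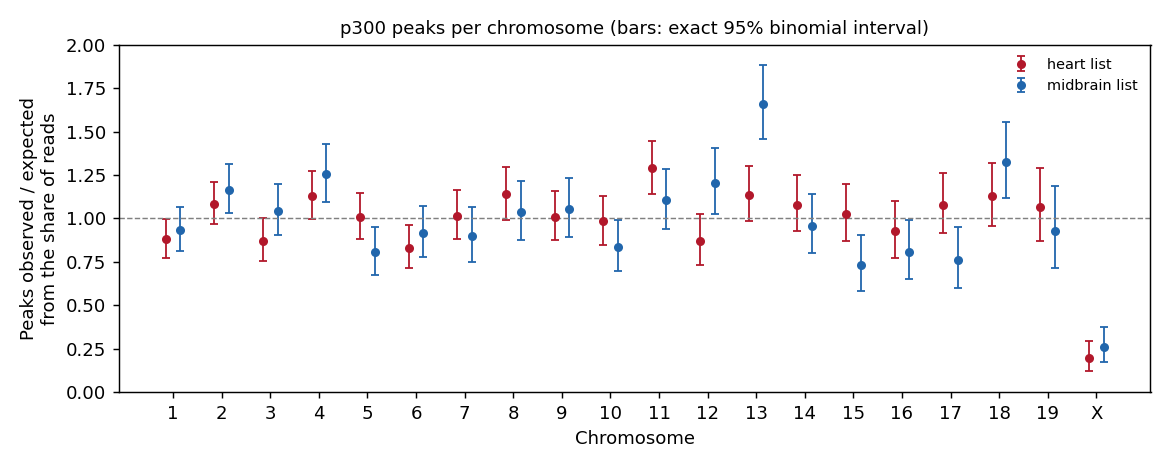
Ratio of observed peaks to the number predicted from the share of reads (vertical axis) for chromosomes 1 to 19 and X (horizontal axis); points are the heart list in red and the midbrain list in blue, and bars are exact 95% binomial intervals of counting error. Chromosome X lies lowest in both lists (0.194 and 0.260), and chromosome 13 lies highest for the midbrain (1.66).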

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

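The limit of 15 rpm that defines dense windows, and so each test on them, was chosen after the reads had been seen. Neither measure was compared with control samples, and each is listed because it lies outside the peaks and above what a count of 0 allows (0.000230% of the heart library and 5.11e-05% of the midbrain library).

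Reads on chromosome M made up 0.154% of the heart library (2011 reads, interval 0.148 to 0.161) and 0.0463% of the midbrain library (2718 reads, interval 0.0446 to 0.0481). The heart share was 3.33 times the midbrain share (interval 3.14 to 3.53), a counting interval for 1 library per tissue.

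Windows of 500 bp with at least 15 rpm held 0.446% of the heart reads in 65 windows (interval 0.434 to 0.457) and 0.112% of the midbrain reads in 36 windows (interval 0.109 to 0.115). Of these, 33 windows were dense in both libraries, and no dense window overlapped a listed peak. The region with the most heart reads, on chromosome 17 at 39979501 to 39986000 (mm9), had 1941 rpm in the heart and 155 rpm in the midbrain, a ratio of 12.5 (interval 11.6 to 13.5). A region on chromosome 9 at 3000001 to 3038500 had 961 and 837 rpm, a ratio of 1.149 (interval 1.08 to 1.22). On chromosome 2 at 98502001 to 98507500 the values were 994 and 488 rpm, a ratio of 2.04 (interval 1.91 to 2.18). These regions were picked for their high counts. At most 1 read is kept per position and strand, which holds down the count of the library with more reads in such a region most, and the ratios are not corrected for this ceiling.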

How the results depend on the processing

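The tests with a 150 bp shift and with joined peaks were chosen after the result was seen. Of 65 alternatives, 13 could not move a value: keeping repeated reads changes nothing because no position repeats, and equal list lengths leave the midbrain list as it is. They say nothing about stability, and the shares of peaks on chromosome X had no other alternative. Of the other 52, 28 stayed within the interval of the reported value or within 1.5 times a count, 24 moved and none turned a direction. That none turned says little about stability. Peak numbers, widths and shares have no direction, and ratios at a library's own peaks were picked in its favour. The better-ranked part of each list held 1798 heart peaks (median width 739 bp) and 1393 midbrain peaks (960 bp). In that part, heart-only enrichment was 9.89 for heart and 1.68 for midbrain reads, midbrain-only enrichment was 7.13 for midbrain reads, and peaks took 1.08% of heart and 0.667% of midbrain reads, from fewer peaks by construction. A reciprocal overlap of 50% gave 2.06% shared heart peaks. Thinning the midbrain reads gave 1148 heart-side intervals in place of 3182, from fewer reads by construction, and a heart-only ratio of 9.59. The coverage track gave heart over midbrain ratios of 8.55 at heart-only and 0.250 at midbrain-only peaks. A shift of 150 bp gave 0.253 at midbrain-only peaks, where midbrain enrichment was 6.22. Flanks at 10 to 20 kb gave 10.4 and 1.66 at heart-only peaks and 7.44 for midbrain reads at midbrain-only peaks. Within 100 kb, 57.8% of heart and 52.8% of midbrain peaks had a neighbour. Joined peaks gave 40.0% and 33.9%, and heart peaks taken to the midbrain list length 41.3%. Where no construction is named, the cause was not tested.

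No paired analysis was possible because each tissue had 1 library. Alternatives for gene lists, start sites and motifs were not run. The median heart peak holds 6 reads, which limits the precision of ratios at single peaks.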

Other observations

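The tests chosen after the result was seen are those of peaks near the other list, of reads per chromosome, of the read requirement of the heart list, and of the windows above chance in the heart against the midbrain. The other tests below had their bounds set before their values were known.

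Tissue-only peaks of the heart and the midbrain also lay near each other somewhat more often than in random placements. Of the heart-only peaks, 493 (14.3%, interval 13.2 to 15.5) had a midbrain-only peak within 50 kb, against 10.4% in random placements (range 8.57 to 12.7). Of the midbrain-only peaks, 465 (17.7%, interval 16.2 to 19.2) had a heart-only peak within 50 kb, against 13.3% (range 10.8 to 16.0). These values are 1.38 and 1.33 times the random means. They leave out the overlapping peaks of the lists, so they are not comparable with the clustering of peaks within a list. The placements and the intervals treat peaks as independent. Because peaks cluster, the random ranges and the intervals are too narrow for an excess of this size to be judged by them.

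Reads were spread over the chromosomes in slightly different shares. Chromosome X took 2.99% of the heart reads and 3.71% of the midbrain reads, a ratio of 0.807 (interval 0.799 to 0.816). Chromosome Y gave 0.789 (interval 0.677 to 0.916), chromosome 11 gave 1.14 (interval 1.14 to 1.154) and chromosome 3 gave 0.920 (interval 0.913 to 0.927). Chromosome 17, which holds the dense region with the most heart reads, gave 1.128 (interval 1.117 to 1.139). The other autosomes lay between 0.933 (chromosome 14) and 1.085 (chromosome 19). These intervals cover counting error only.

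The heart list holds more peaks (3597 against 2786) although its library holds 4.50 times fewer reads. Moving each heart read at random within its 10 kb bin left 22.3% of the 500 bp windows with 5 or more reads, which lies between the bounds of 10% and 50% set beforehand, so a part of such windows is at the level of chance. Chance as the whole cause is not borne out, because the windows above the chance level were 3.80 times as many in the heart as in the midbrain thinned to the same depth (lowest ratio over the draws 3.58). At equal depth, 3349 heart windows reached 5 reads against 1026 in the thinned midbrain, a ratio of 3.26 (interval 3.04 to 3.50). Heart reads thus group more, but heart peaks are themselves groups of these reads, and the windows were not shown to be bound sites. A larger share of heart fragments at bound sites therefore remains possible without separate support. Tissue and library preparation as its source are not separable with 1 library each. The test of a lower read requirement decided nothing, because 94.02% of heart peaks hold fewer reads than the 5th percentile of midbrain peaks (11 reads) but so do 94.3% of midbrain peaks after thinning to the heart depth, while on the library scale the 5th percentile was higher for heart peaks (3.07 rpm) than for midbrain peaks (1.87 rpm).

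Reads of the other tissue lay above their flanks at peaks found in only 1 list. If a few peaks just under the calling threshold carried this, leaving out the 10% of peaks with the most such reads would end it. It did not: the density over flanks that was left was 1.34 for midbrain reads at heart-only peaks and 1.37 for heart reads at midbrain-only peaks. Relative to random placements trimmed alike, these were 1.70 times higher (range 1.62 to 1.78) and 2.40 times higher (range 2.19 to 2.70). Those ratios overstate the excess. Trimming brought the random means down to 0.783 and 0.570, which peaks at the level of their flanks would also exceed. Weak p300 binding in both tissues and easier recovery of open chromatin remain possible explanations, and no input library was used here to separate them.

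Chromosome X held few peaks in both lists. Its read density was 0.477 times that of the autosomes in the heart and 0.596 times in the midbrain, so fewer reads per site could leave more sites below the calling threshold. Autosomal peaks were thinned to that density and kept if they still held at least 4 heart or 11 midbrain reads. They predicted ratios of observed to expected peaks of 0.711 in the heart (range 0.676 to 0.748) and 0.819 in the midbrain (range 0.801 to 0.845). The ranges cover the random thinning only. The share of peaks kept depends on the cutoff, the authors' threshold is not known, and no other cutoff was run. The observed ratios, 0.194 (interval 0.120 to 0.297) and 0.260 (interval 0.172 to 0.378), lie below these ranges. Lower read density alone therefore does not account for them at these cutoffs, and a stricter threshold was not tested. The calling procedure and a true scarcity of p300 sites on this chromosome were not tested.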
